A study of Homo sapiens with 20 samples.

How the data were processed

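RNA from 5 established cell lines of classical Hodgkin lymphoma (SUP-HD1, UHO-1, L1236, L428 and KM-H2) was measured after 24 h with 4-hydroxytamoxifen (4-OHT) or with ethanol vehicle. Every line expressed FOXO1(3A)ER, a constitutively active mutant of FOXO1 joined to the ligand-binding domain of the oestrogen receptor. The 20 arrays formed 10 groups of 2, and the group of each array was taken from its title. The protocol text of the labels gives a dose of 200 µM 4-OHT but names KM-H2 and L428 cells with another fusion protein, so the dose is quoted only as labelled. The same text says that the experiment was done 2 times. Nothing else says that the 2 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, part of which may be technical.

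Per the labels' protocols and the design text of the series, total RNA was amplified and labelled by the whole transcript sense target assay and hybridised to Affymetrix Human Gene 1.0 ST arrays. The authors' deposited values are log2 expression values from the robust multichip average (RMA), computed with Affymetrix Expression Console, per the labels and the design text. RMA corrects the background, normalises the distribution of values between arrays and summarises the probes of a probe set. The version of RMA and the annotation level were not given in the sources used here. The values showed that the arrays had been normalised in 2 separate runs. Sorted values differed by at most 0.253 log2 units between arrays of KM-H2 and L428 and by at most 0.204 between arrays of L1236, UHO-1 and SUP-HD1. Between the sets the largest difference was never below 0.712. Medians ran from 5.67 to 5.71 in the 8 arrays of the first set and from 6.26 to 6.41 in the 12 arrays of the other. Levels were therefore compared between lines only within a set, and each line was compared with its own vehicle arrays. The floor and the ranges of signal used below took the same log2 values in both sets, so they do not mark equal levels. Below 5 lay 2832 genes in KM-H2 but 956 in L1236. For arrays there is no read depth, and the number of arrays limits the precision.

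The table held 33268 probe sets. Of these, 19457 had exactly 1 gene symbol in the platform annotation, 1751 had several and 12060 were not listed there and stay unnamed. The Entrez identifiers of 19426 of the named probe sets were found in the RefSeq gene table of GRCh38.p14, which changed 0 symbols. The genome build of the array was not given in the sources used here, so that table served only for names and for which genes neighbour each other, and no coordinates are printed. For the 767 genes with several probe sets, the one with the highest mean over the 20 arrays was used. Among genes named in the text, 11 had several probe sets, and in 0 of these did the probe sets disagree in the sign of the average change. A gene was kept if its log2 value was at least 5 in at least 2 arrays, which left 15850 of 18416 genes. The 2 histone genes H4C14 and H4C15 held the same values in all arrays and cannot be told apart.

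Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3. A model with the 10 group means was fitted to all 20 arrays (lmFit, then eBayes with an intensity trend), which left 10 residual degrees of freedom and 11.8 prior degrees of freedom. The contrasts were 4-OHT minus vehicle in each line, the mean of the 5 lines' differences, and an F test of whether the difference varied between lines. P-values were adjusted by the Benjamini-Hochberg method over the 15850 genes of each contrast, and a gene passed at an adjusted p below 0.05. Adjusted p-values given for genes come from limma, and errors are its standard errors, which share 1 spread over all groups. The tests, the gene lists and the rule for naming genes were fixed before the data were examined.

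The 25 lists were FOXO-induced targets, plasma cell genes, B cell identity genes, germinal centre genes, MHC class II genes, mitosis genes, S phase genes, G1 cyclins, kinases and inhibitors, MYC and ribosome biogenesis genes, NF-kB target genes, JAK-STAT genes, Hodgkin cell markers, BCL2 family genes, insulin and PI3K signalling genes, unfolded protein response genes, autophagy genes, interferon-induced genes, cholesterol synthesis genes, oestrogen-induced genes, lymphocyte migration genes, glycolysis genes, T cell markers, myeloid markers, stromal markers and housekeeping genes. Some genes stood in more than 1 list. Each list was tested against the other genes with limma's camera at a preset correlation between genes of 0.01, two-sided, for the average and for each line, with adjustment over the 25 lists for the average and over the 125 combinations for the lines. Camera was repeated with the correlation estimated from the data. fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, was an alternative. Whether the mean change of a list differed between lines was tested by an F test in limma on the means of the list. Within a list, genes were also counted with p-values adjusted over the list alone.

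Always named were FOXO1, ESR1, PRDM1, CDKN1B, BCL2L11, MYC, BCL6, IRF4, CCND2 and TNFRSF8. For the average, the 15 largest rises and 10 largest falls were named among genes that passed and moved the same way in all 5 lines. For each line, the 3 largest rises and 3 largest falls were named among genes that passed and whose 4-OHT arrays both lay beyond both vehicle arrays. The 8 genes with the widest range of change over the lines were taken from those that passed the F test. Up to 4 members of each list with the smallest adjusted p on average could be named, and other members of a list where it is described.

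The scripts were tested on simulated data in which 200 genes had been changed by known amounts in all lines and 200 others in 1 line, the latter for the F test. At a log2 change of 0.25, the average contrast recovered 46 of 50 genes and a single line (simulated as L428) recovered 10 of 50. At 0.5 they recovered 50 and 36, and at 1 both recovered 50 of 50. The F test recovered 1, 17 and 50 of 50 genes at those sizes. Among 15450 unchanged genes, 23, 13 and 5 were called by the average, the single line and the F test. The simulated noise was independent for each gene and array. These counts therefore leave out correlation between genes and shared deviations of arrays, and false calls may be more frequent in the real data. Alternatives were other floors for low values, quantile normalisation of all arrays together, median centring, cyclic loess within each set of arrays, the replicate number as a block, other settings of eBayes, array weights, all probe sets, other thresholds, each array or line left out, each set of arrays or each line alone, and the 5 lines as the replicates. Figures were drawn with matplotlib.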

Results

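Transcript levels were measured in 5 lines of classical Hodgkin lymphoma, a tumour derived from B cells that has lost much of the B cell programme. The lines were UHO-1, SUP-HD1, L1236, L428 and KM-H2. Each carried FOXO1(3A)ER, a form of the transcription factor FOXO1 that escapes inactivation by AKT and is held inactive until a ligand such as 4-OHT binds the fused oestrogen receptor domain. Cells received 4-OHT or ethanol vehicle for 24 h, and each arm of each line was measured on 2 arrays, 20 arrays in all. The study asks which transcripts respond to FOXO1 activity in these cells, in which FOXO1 has been studied as a tumour suppressor and as a link to PRDM1, the regulator of plasma cell differentiation. Median signals ran from 5.67 to 5.71 log2 units in the arrays of KM-H2 and L428 and from 6.26 to 6.41 in the other 12, which had been normalised separately. The number of arrays limits the precision: the SD of the difference between the 2 arrays of an arm, over all genes, lay between 0.133 and 0.204 log2 units. No line without the fusion protein was treated with 4-OHT among the arrays used here, so an effect of 4-OHT itself cannot be separated from that of FOXO1.

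FOXO1 transcripts (probe set 7971177) did not pass the test on average, with a change of -0.078 ± 0.036 log2 units (SE, n = 10 arrays per arm, adjusted p = 0.0925). FOXO1 rose by 0.27 ± 0.08 in L1236 (adjusted p = 0.0161) and fell by 0.33 ± 0.08 in UHO-1 (0.00478) and by 0.34 ± 0.08 in SUP-HD1 (0.0104), and it was not called in KM-H2 or L428. ESR1, the gene from which the fused domain comes (probe set 8122843), changed by -0.13 ± 0.056 on average (adjusted p = 0.0632) and passed only in UHO-1, at -0.35 ± 0.13 (0.0455). The switch acts on the protein, and whether these probe sets read the fusion transcript was not determined, so neither gene checks the treatment. These calls depended on single arrays: FOXO1 was lost without UHO-1 vehicle 2 (adjusted p = 0.0519), without L1236 vehicle 2 or 4-OHT 2 (up to 0.229) and without SUP-HD1 vehicle 2 or 4-OHT 2 (up to 0.168), and the ESR1 call in 9 of 20 fits that left out 1 array. Other scalings also ended the ESR1 call (adjusted p from 0.0955 to 0.35), as did no floor (0.0515) and the mean of its 2 probe sets (-0.208, adjusted p = 0.133), the other of which changed by -0.011 on average. Median centring ended the FOXO1 call in L1236 (0.0779), and eBayes without a trend ended it there (0.0535) and in SUP-HD1 (0.0544). The average of FOXO1 passed without L1236 (-0.17, adjusted p = 0.00187), without L428 (0.0451), in the 3 lines normalised together (-0.135, 0.0261) and in 4 of the 20 fits, but was 0.0069 in KM-H2 and L428 alone. That of ESR1 passed without L1236 (0.0468), in 5 of the 20, with quantile normalisation (0.048), with median centring (0.0482) and without a trend (0.0482).

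On average over the 5 lines, RGS1, FBXO32, CBLB, PRDM1 and FOXP1 rose most with 4-OHT among genes higher in every line, and MYC fell. RGS1, which restrains chemokine receptor signalling, rose by 2.48 ± 0.047 log2 units, 5.57-fold (SE, n = 10 arrays per arm, adjusted p = 7.18e-21). FBXO32, a ubiquitin ligase subunit and a classical FOXO target, rose by 2.24 ± 0.037 (4.73-fold), CBLB, a ubiquitin ligase that dampens antigen receptor signalling, by 2.08 ± 0.054, PRDM1 by 1.91 ± 0.053 and FOXP1, another forkhead factor of B cells, by 1.90 ± 0.039. After these 5 came GCSAM (1.62), PRL (1.61), DEPP1 (1.59), RIPOR2 (1.57), FERMT2 (1.48), ENPP2 (1.44), TP53INP1 (1.37), ABLIM1 (1.36), LGR4 (1.34) and PLPP3 (1.34), all with adjusted p of 1.02e-14 or less. Outside UHO-1, PRL stayed below the floor of 5 in both arms, so its average and rank rest partly on signals near background. MYC fell by 1.01 ± 0.034 (2.02-fold, adjusted p = 2.82e-16). Among genes lower in all 5 lines, the next largest falls were those of HSPA4L (-0.73), a heat shock protein, BCL11A (-0.73), a lymphoid transcription factor, SLC27A2 (-0.71), IL2RB (-0.70), a cytokine receptor chain, EPHB1 (-0.69), TFAP4 (-0.69), a transcription factor and MYC target, GRK5 (-0.65), MARVELD2 (-0.63) and LTA (-0.62), a cytokine of the TNF family. The fall of GRK5 depends on the probe set, as the other one for this gene changed by -0.094.

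In all, 6122 of 15850 genes passed on average, 2765 higher and 3357 lower with 4-OHT (limma, 20 arrays). The balance depended on scaling: it was 2337 higher and 3458 lower after median centring, 3056 and 3051 after cyclic loess within each set, and 3344 and 2789 after cyclic loess on the tested genes. Most changes were small: 50 rises and 1 fall, that of MYC, reached 1 log2 unit. The means of all 5 lines moved the same way for 965 of the higher and 1298 of the lower genes. Called in each of the 5 lines were 53 genes that rose and 38 that fell. Independent lists of those sizes would share 0.077 and 0.13 if every gene were equally likely to be called, which was not the case. Among the 53 were PRDM1, CDKN1B, FOXP1, CBLB, RGS1, IGF1R, RICTOR and PIK3IP1, and among the 38 were MYC, FBL, WDR43, HSPA4L, PAICS and MT2A, of which PAICS and MT2A were chosen after their values were seen. These p-values describe the arrays of these 5 lines. With the 5 lines as the replicates, limma called 0 genes, with 2373 at an unadjusted p below 0.05.

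**Figure D1:**
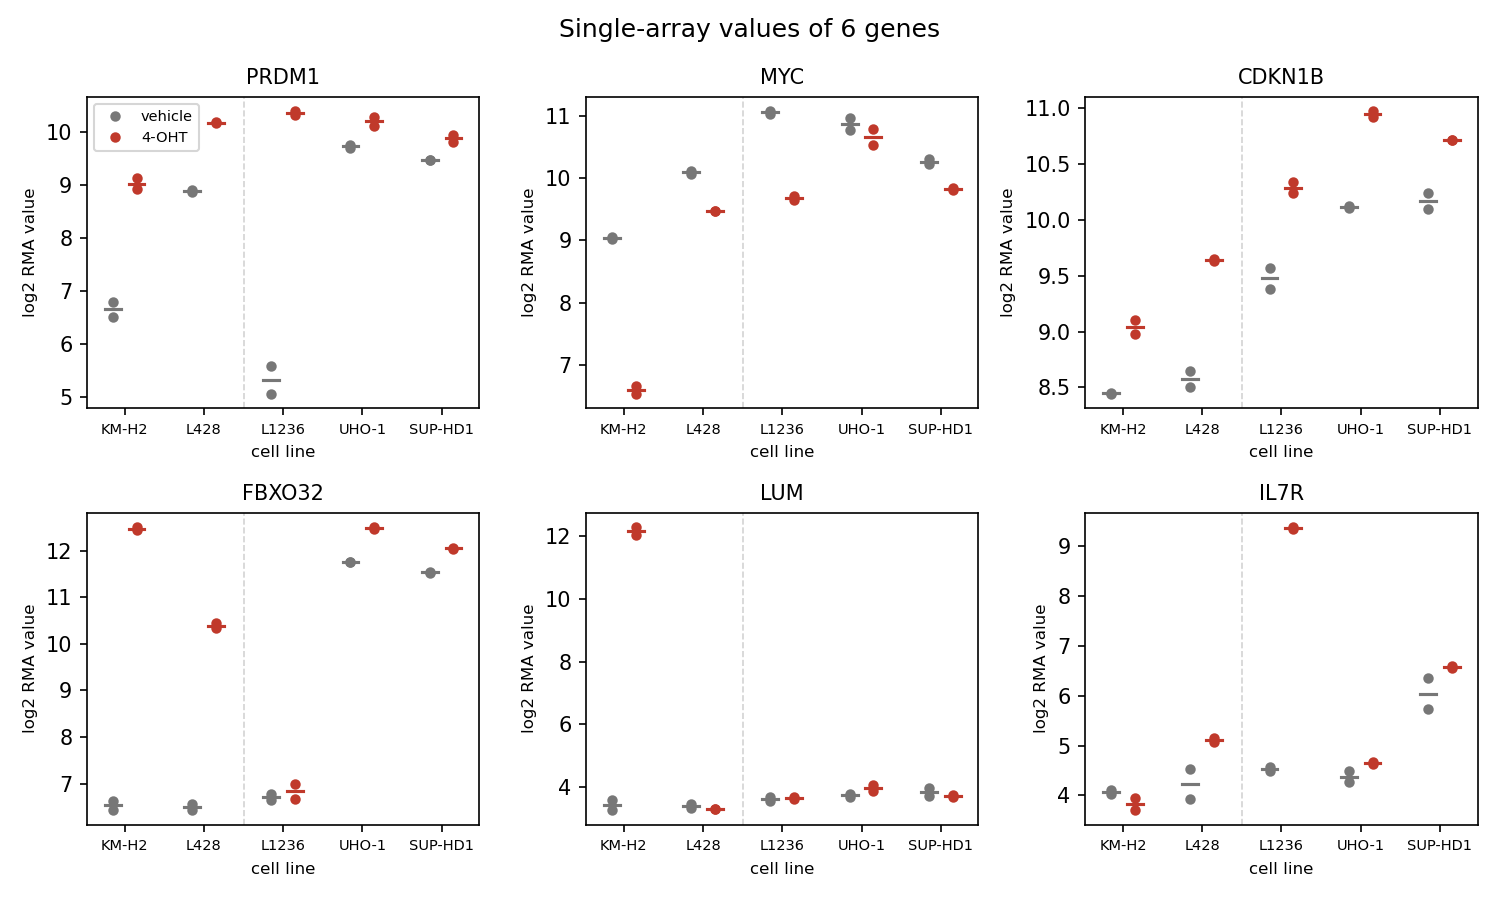
Log2 RMA values (vertical axes) of 6 genes in the 5 cell lines (horizontal axes), with 1 point per array, grey for vehicle and red for 4-OHT, and a bar at the mean of each group of 2. The dashed line parts the 2 sets of arrays that were normalised separately, so levels compare only on one side of it; LUM reached 12.2 in KM-H2 with 4-OHT from 3.41 in vehicle, and IL7R reached 9.37 in L1236 from 4.54.

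The always named genes took several courses. CDKN1B, the cell cycle inhibitor p27, rose by 0.77 ± 0.032 on average (adjusted p = 9.23e-15) and in each of the 5 lines, by between 0.56 ± 0.071 in SUP-HD1 and 1.07 ± 0.071 in L428. BCL2L11, the pro-apoptotic protein BIM, rose by 0.58 ± 0.045 (4.56e-10) and was called in 3 lines. CCND2, cyclin D2, fell by 0.57 ± 0.046 (9.01e-10) and was called in 4. TNFRSF8, the Hodgkin cell antigen CD30, fell by 0.77 ± 0.041 (9.04e-13), by 1.45 ± 0.091 in L428, 1.38 ± 0.091 in KM-H2 and 0.85 ± 0.091 in UHO-1. BCL6, the germinal centre repressor that opposes PRDM1, rose by 0.32 ± 0.032 on average (2.59e-08), but it rose by 1.10 ± 0.071 in L428, 0.81 ± 0.071 in UHO-1 and 0.45 ± 0.071 in SUP-HD1 and fell by 0.66 ± 0.071 in L1236 (2.58e-07). IRF4, a factor of activated B cells and plasma cells, changed by -0.055 ± 0.039 and was not called on average (0.304); its average passed without L1236 (-0.085, adjusted p = 0.0327), without L1236 vehicle 2 (0.0419) and in KM-H2 and L428 alone (-0.175, 0.00889), but was 0.025 in the other 3 lines (0.768) and 0.0097 without L428 (0.895).

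The FOXO-induced targets rose as a group. Of 31 tested members, 22 rose, 1 fell and 8 did not pass, and adjusted over the list alone 24 rose and 1 fell. Their median change was 0.33 log2 units (camera adjusted p = 3.08e-16 on average), and the shift also held with an estimated correlation, at an adjusted p of 0.00076. After FBXO32 the members with the smallest p were SESN3, a stress-induced inhibitor of mTORC1, at 1.27 ± 0.035, CCR7, a chemokine receptor for homing to lymph nodes, at 0.73 ± 0.025, and TNFSF10, the death ligand TRAIL, at 1.04 ± 0.043. The list was higher in every line, with medians of 0.082 in KM-H2, 0.43 in L428, 0.32 in L1236, 0.31 in UHO-1 and 0.18 in SUP-HD1, and each line passed with either correlation (adjusted p of 0.033 or less with an estimated correlation). Its mean changes were 0.63 in KM-H2, 0.71 in L428, 0.55 in L1236, 0.33 in UHO-1 and 0.24 in SUP-HD1. KM-H2 thus had the lowest median but not the lowest mean, which there rested on large rises of part of the members. The mean change of the list differed between lines (F test adjusted p = 3.3e-07). PMAIP1, a pro-apoptotic member that rose by 0.48 ± 0.036 on average, lay at -0.055 in the 3 lines normalised together (adjusted p = 0.45).

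Signalling and recycling lists were also higher with 4-OHT on average. Some share members with the FOXO-induced targets, such as CCR7 and KLF2 of the migration list and PIK3IP1 of the insulin list. Those calls are therefore not independent of that of the FOXO list. Of 9 lymphocyte migration genes, 6 rose and 1 fell, with the same counts adjusted over the list alone (median 0.22, camera adjusted p = 0.00159, and 0.048 with an estimated correlation). CXCR4, the receptor of CXCL12, rose by 0.44 ± 0.032 and CCR6 by 0.29 ± 0.052. That shift rested on L1236, without which the adjusted p was 0.312 (0.425 in KM-H2 and L428 alone), and in that line KLF2, the regulator of T and B cell trafficking, rose by 2.73 ± 0.087. Of 14 autophagy genes, 9 rose and 0 fell, and the same 9 and 0 resulted when adjusted over the list alone (median 0.12, camera adjusted p = 0.00456, adjusted p = 0.25 with an estimated correlation). MAP1LC3B, the autophagosome marker LC3B, rose by 0.32 ± 0.051, WIPI1 by 0.26 ± 0.048 and ATG5 by 0.14 ± 0.032, the last not called without KM-H2 (adjusted p = 0.0809). In the 3 lines normalised together, WIPI1 (0.087, adjusted p = 0.286) and ATG5 (0.086, 0.118) were not called.

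Of 18 insulin and PI3K signalling genes, 9 rose and 3 fell, or 9 and 4 adjusted over the list alone (median 0.082, camera adjusted p = 0.0247, adjusted p = 0.25 with an estimated correlation). PIK3IP1, an inhibitor of PI3K, rose by 1.08 ± 0.06, the growth factor receptor IGF1R by 0.71 ± 0.038 and RICTOR, a subunit of mTORC2, by 0.64 ± 0.041, while the kinase AKT2 fell by 0.17 ± 0.027. Of 14 JAK-STAT genes, 7 rose and 5 fell, with the same counts adjusted over the list alone (median 0.083, camera adjusted p = 0.0478, adjusted p = 0.25 with an estimated correlation). The kinases PIM1 and PIM2 rose by 0.61 ± 0.033 and 0.56 ± 0.033 and the receptor chain IL4R by 0.51 ± 0.034, whereas SOCS1, the feedback inhibitor of the pathway, fell by 0.76 ± 0.047. The insulin and PI3K call was lost without UHO-1 (0.0645) or SUP-HD1 (0.0574), and the JAK-STAT call without L1236, UHO-1 or SUP-HD1 (up to 0.133) and in 10 of 20 fits that left out 1 array (up to 0.0641). A floor of 8 ended both (0.39 and 0.125), as did KM-H2 and L428 alone (0.431 and 0.599). A floor of 6 (0.0625), either cyclic loess (0.0599 and 0.0645) or the replicate number as a block (0.0653) ended the JAK-STAT call.

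**Figure D2:**
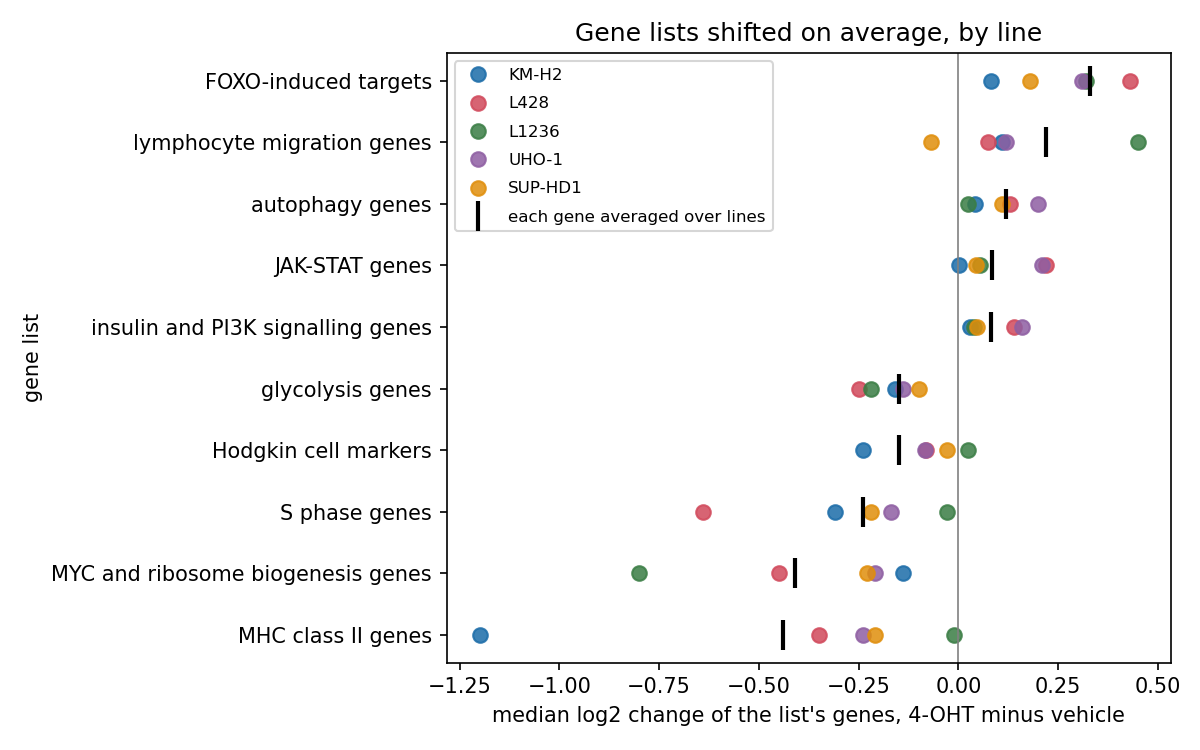
Median log2 change of the tested genes of a list, 4-OHT minus vehicle (horizontal axis), for the 10 lists shifted on average (vertical axis); points are the 5 lines, and black ticks are medians of the changes after each gene was averaged over the lines, not means of the points. MHC class II genes had a median of -1.2 in KM-H2 and -0.012 in L1236, and FOXO-induced targets lay above 0 in every line.

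Genes of ribosome production and DNA replication were lower with 4-OHT on average. Of 18 MYC and ribosome biogenesis genes, 17 fell and 1 rose, with the same counts adjusted over the list alone (median -0.41, camera adjusted p = 3.87e-11, adjusted p = 0.096 with an estimated correlation). FBL, the rRNA methyltransferase fibrillarin, fell by 0.32 ± 0.02, WDR43, a factor of ribosome assembly, by 0.40 ± 0.028 and MYBBP1A, a nucleolar protein, by 0.40 ± 0.029. In single lines the list was lowest in L1236 (median -0.80, adjusted p = 7.5e-18, and 0.033 with an estimated correlation) and was called lower in the other 4 as well, at adjusted p of 0.0049 or less, none of which held with an estimated correlation (adjusted p = 0.24 or more). Of 22 S phase genes, 18 fell and 1 rose, or 18 and 2 adjusted over the list alone (median -0.24, camera adjusted p = 1.36e-06, adjusted p = 0.25 with an estimated correlation). The replicative helicase subunits MCM3, MCM2 and MCM4 fell by 0.45 ± 0.028, 0.39 ± 0.028 and 0.34 ± 0.024, and TYMS, thymidylate synthase, by 0.34 ± 0.026. The S phase median was -0.64 in L428, -0.31 in KM-H2 and -0.22 in SUP-HD1, each called lower, but none of these held with an estimated correlation (adjusted p = 0.24, 0.37 and 0.32). The list was not called in UHO-1 (-0.17, adjusted p = 0.099) or in L1236 (-0.029, adjusted p = 0.56), and in L1236 the test pointed up.

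MHC class II, Hodgkin and glycolytic genes were lower as groups too. All 7 tested MHC class II genes fell, also adjusted over the list alone (median -0.44, camera adjusted p = 0.000112, adjusted p = 0.15 with an estimated correlation). The listed genes HLA-DRA, HLA-DRB1 and CD74 had no probe set with their symbol alone and were not tested. HLA-DMB and HLA-DMA, which load peptides, fell by 0.50 ± 0.05 and 0.44 ± 0.04, and HLA-DPB1 and HLA-DPA1, which present them, by 0.49 ± 0.036 and 0.45 ± 0.037. The fall was largest in KM-H2 (median -1.2, adjusted p = 2.2e-08, and 0.045 with an estimated correlation), where HLA-DPB1 fell by 1.59 ± 0.082. Of 22 Hodgkin cell markers, 12 fell and 6 rose, or 13 and 6 adjusted over the list alone (median -0.15, camera adjusted p = 0.0465, adjusted p = 0.33 with an estimated correlation). With TNFRSF8 and LTA, the chemokine CCL5 fell by 0.91 ± 0.036 and the actin bundler FSCN1 by 0.40 ± 0.038. That call was lost without KM-H2 (0.309), in the 3 lines normalised together (0.589), in 6 of 20 fits that left out 1 array (up to 0.0875), with a floor of 6 (0.0543) or 8 (0.124) and with the replicate number as a block (0.0623). FSCN1 was not called in those 3 lines (-0.055, adjusted p = 0.345).

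Of 17 glycolysis genes, 12 fell and 2 rose, with the same counts adjusted over the list alone (median -0.15, camera adjusted p = 0.00456, adjusted p = 0.33 with an estimated correlation). Pyruvate kinase PKM fell by 0.33 ± 0.019, hexokinase HK2 by 0.45 ± 0.034 and enolase ENO1 by 0.25 ± 0.019. The glucose transporter SLC2A1 was called higher on average, by 0.41 ± 0.025. It rose by 2.37 ± 0.056 in KM-H2 and 0.23 ± 0.056 in L428, but fell by 0.20 ± 0.056 in UHO-1 (adjusted p = 0.0127) and fell by 0.24 ± 0.056 in SUP-HD1 (0.011). That average rested on KM-H2, without which it was -0.082 (adjusted p = 0.0347), and in the 3 lines normalised together it was -0.186 (0.000689). Both falls were lost with median centring (0.155 and 0.0776), each in 2 fits that left out 1 array of its line (up to 0.152 and 0.148), and that in SUP-HD1 also without a trend (0.0681) or with its 4 arrays alone (0.0738). Of 100 groupings of the arrays within lines, the real one included, 9 called at least as many lists as the 10 found here, the highest other count being 12, so the number of lists by itself does not exclude chance.

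The remaining 15 lists did not pass on average. Plasma cell genes had 5 rises and 3 falls among 13 tested, also adjusted over the list alone (camera adjusted p = 0.156). The listed genes TNFRSF17, JCHAIN and SLAMF7 did not reach the floor and were not tested. The mean change of that list was 0.19 and its test pointed up, but its median was -0.0097. Beside PRDM1, the ectoenzyme CD38 rose by 0.79 ± 0.068 and ELL2, an elongation factor of secretory B cells, by 0.28 ± 0.035, while FKBP11, a chaperone of secretory cells, fell by 0.38 ± 0.044. ELL2 was not called in the 3 lines normalised together (0.102, adjusted p = 0.154). CD38 rose by 1.77 ± 0.15 in UHO-1, 1.32 ± 0.15 in L428 and 0.93 ± 0.15 in L1236. Among 16 B cell identity genes 8 fell and 2 rose, also adjusted over the list alone (median -0.12, adjusted p = 0.119). Beside BCL11A, the kinase LYN fell by 0.24 ± 0.042 and FCRLA by 0.38 ± 0.057, both lost without KM-H2 (adjusted p = 0.182 and 0.343) and in the 3 lines normalised together (0.123 and 0.114). In KM-H2 the B cell list was lower (median -0.23, adjusted p = 3.2e-05, and 0.013 with an estimated correlation), and it passed on average without L1236 (0.0125) or L428 (0.0437) and in KM-H2 and L428 alone (0.00278). The lower average rested on KM-H2, without which the mean was 0.0036 (adjusted p = 0.876), and in the 3 lines normalised together it was 0.017 (0.9). Among 8 germinal centre genes 4 rose and 1 fell, or 4 and 2 adjusted over the list alone (median 0.11, camera adjusted p = 0.0925, adjusted p = 0.25 with an estimated correlation). GCSAM, BCL6, the repressor BACH2 (0.57 ± 0.084) and RGS13 (0.39 ± 0.064) rose, the last not called in the 3 lines normalised together (0.158, adjusted p = 0.106), and the list passed as higher with no floor (adjusted p = 0.0362), a floor of 6 (0.0416) or a floor of 8 (0.0143).

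Mitosis genes had 3 rises and 11 falls among 22, also adjusted over the list alone (median -0.092, adjusted p = 0.119), and lines went opposite ways. The list was higher in L1236 (median 0.25, adjusted p = 6.3e-07, adjusted p = 0.32 with an estimated correlation) and lower in L428 (-0.49, 6.2e-09, adjusted p = 0.26 with an estimated correlation) and SUP-HD1 (-0.15, 0.0017, adjusted p = 0.49 with an estimated correlation). FOXM1, a driver of mitotic genes, fell by 0.21 ± 0.027 on average and AURKB by 0.21 ± 0.031, the latter not called without L428 (adjusted p = 0.0624). Neither was called in the 3 lines normalised together (-0.092 and -0.051, adjusted p = 0.058 and 0.369). The mitosis list passed as lower without L1236 (0.00107), KM-H2 (0.023) or SUP-HD1 vehicle 2 (0.0486) and in KM-H2 and L428 alone (0.000341), but its mean was 0.029 without L428 (adjusted p = 0.373) and 0.02 in the 3 lines normalised together (0.575). G1 cyclins, kinases and inhibitors had 2 rises and 3 falls among 11, also adjusted over the list alone (median -0.056, adjusted p = 0.9), with the kinase CDK4 down by 0.32 ± 0.022.

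Among 18 NF-kB target genes 5 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.58, mean 0.054, median -0.045). CD83, an activation marker, rose by 0.72 ± 0.027 and TNFAIP3, the feedback inhibitor A20, by 0.34 ± 0.029, while the cytokine chain EBI3 fell by 0.35 ± 0.049, a fall not called without KM-H2 (adjusted p = 0.583) or in the 3 lines normalised together (0.356). The list was lower in KM-H2 (median -0.39, adjusted p = 0.005, adjusted p = 0.23 with an estimated correlation) and higher in SUP-HD1 (0.15, 5.9e-08, and 0.015 with an estimated correlation), and without KM-H2 it passed as higher on average (0.00176), as it did in the 3 lines normalised together (0.000665), while its mean was -0.083 in KM-H2 and L428 alone and 0.0067 without SUP-HD1. Among 14 BCL2 family genes 4 rose and 4 fell, or 4 and 5 adjusted over the list alone (adjusted p = 0.623, mean 0.048, median -0.022), with MCL1 up by 0.46 ± 0.036 and BCL2L1 down by 0.18 ± 0.031, the latter not called in those 3 lines (adjusted p = 0.148).

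Unfolded protein response genes had 5 rises and 5 falls among 18, or 6 and 6 adjusted over the list alone (median 0.017, adjusted p = 0.725). DNAJC3 and EDEM1 rose by 0.44 ± 0.044 and 0.30 ± 0.038, the latter not called without L1236 (adjusted p = 0.357), and the disulfide isomerases PDIA6 and PDIA4 fell by 0.26 ± 0.023 and 0.25 ± 0.029. Interferon-induced genes had 2 rises and 9 falls among 19, also adjusted over the list alone (median -0.17, adjusted p = 0.442), with IFIT2 up by 0.94 ± 0.053 and IFI44L down by 0.54 ± 0.075. The list passed as lower in KM-H2 and L428 alone (mean -0.211, adjusted p = 0.0165), but its mean was 0.02 in the other 3 lines (0.575) and -0.011 without KM-H2 (0.895). Cholesterol synthesis genes had 2 rises and 8 falls among 13, or 2 and 9 adjusted over the list alone (median -0.11, adjusted p = 0.169). The sterol sensor INSIG1 and the desaturase SC5D rose by 0.50 ± 0.029 and 0.47 ± 0.036, and the enzymes DHCR7 and EBP fell by 0.39 ± 0.034 and 0.34 ± 0.03. The cholesterol list was lower in L1236 (median -0.43, adjusted p = 4.1e-05, adjusted p = 0.25 with an estimated correlation).

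Oestrogen-induced genes, which could respond to 4-OHT through a native receptor, had 1 rise and 1 fall among 8 (median -0.034, adjusted p = 0.935). T cell markers had 1 rise and 1 fall among 10 (median -0.066, adjusted p = 0.798), and myeloid markers 1 and 1 among 6 (adjusted p = 0.935, mean 0.036, median -0.022). Stromal markers had 2 rises and 1 fall among 8 (median 0.02, adjusted p = 0.124) and passed as higher without UHO-1 (0.0402) and in KM-H2 and L428 alone (0.0259), while their mean in the 3 lines normalised together was -0.022. Housekeeping genes had 3 rises and 4 falls among 8 (median -0.063, adjusted p = 0.935). In these 5 lists the counts adjusted over the list alone were the same. With an estimated correlation, none of the 15 lists passed on average, and their adjusted p ran from 0.25 to 0.95.

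PRDM1, which drives B cells towards plasma cells, was called higher in each line, and the size of the rise differed widely (F test adjusted p = 4.62e-15). It rose by 5.04 ± 0.12 in L1236, from a level of 5.33 to 10.4 (SE, n = 2 arrays per arm, adjusted p = 2.67e-18), by 2.37 ± 0.12 in KM-H2 (3.56e-13), by 1.29 ± 0.12 in L428 (1.39e-08), by 0.47 ± 0.12 in UHO-1 (0.00696) and by 0.41 ± 0.12 in SUP-HD1 (0.043). Within the set of 3 lines normalised together, vehicle levels were 5.33 in L1236, 9.47 in SUP-HD1 and 9.73 in UHO-1. MYC fell by 2.44 ± 0.076 in KM-H2, 1.37 ± 0.076 in L1236, 0.61 ± 0.076 in L428, 0.43 ± 0.076 in SUP-HD1 and 0.21 ± 0.076 in UHO-1 (0.0468). The PRDM1 call was lost in 10 of 20 fits that left out 1 array for SUP-HD1 (adjusted p up to 0.338), with median centring there (0.083) and without a trend in eBayes (0.118), and in 2 for UHO-1 (up to 0.0859). The MYC call in UHO-1 was lost in 10 of 20 (up to 0.514), with median centring (0.225), with no floor (0.0533), without a trend (0.0909) and with the 4 arrays of UHO-1 alone (0.0878).

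In KM-H2, the largest rises among genes whose arms did not overlap were those of LUM, FBXO32 and NTS, and the largest falls those of CCL5, LGALS2 and CR2. LUM, an extracellular matrix proteoglycan, rose by 8.77 ± 0.12 log2 units, from 3.41, below the floor of 5, to 12.2 (SE, n = 2 arrays per arm, adjusted p = 2.18e-23). FBXO32 rose by 5.94 ± 0.084 and NTS, the peptide neurotensin, by 4.33 ± 0.12, while DCN, the proteoglycan decorin, rose by 3.39 ± 0.11 from 3.37. CCL5 fell by 3.64 ± 0.08, LGALS2, a galectin, fell by 3.01 ± 0.11, and CR2, the complement receptor CD21 of B cells, fell by 2.59 ± 0.12. In total 3535 genes passed, 1592 higher and 1943 lower, and 269 and 164 of these by at least 1 log2 unit. Glycolysis genes (median -0.16), interferon-induced genes (-0.15) and Hodgkin cell markers (-0.24) were called lower in this line at adjusted p of 0.027, 0.026 and 4.4e-05, and S phase genes at 8.7e-06. None of these 4 held with an estimated correlation (adjusted p = 0.51, 0.58, 0.22 and 0.37 with an estimated correlation).

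In L428, ENPP2, the lysophospholipase D autotaxin, rose by 4.36 ± 0.13, FBXO32 by 3.89 ± 0.084 and GCSAM, a germinal centre protein that regulates motility, by 3.64 ± 0.11. EHF, an epithelial ETS factor, fell by 2.08 ± 0.21, ENTREP1 fell by 1.96 ± 0.12 and ABCG2, a drug efflux pump, fell by 1.58 ± 0.11 (n = 2 arrays per arm, limma adjusted p of 7.36e-08 or less). In total 4673 genes passed, 1901 higher and 2772 lower, and 247 and 62 of these by at least 1 log2 unit. The balance depended on scaling, with 1471 higher and 2868 lower after median centring and 2406 and 2363 after cyclic loess on the tested genes. Germinal centre genes (median 0.29, adjusted p = 0.02) and autophagy genes (0.13, 0.03) were called higher and S phase genes (-0.64, 4.3e-10) and glycolysis genes (-0.25, 0.023) lower. None of these held with an estimated correlation (adjusted p = 0.22, 0.43, 0.24 and 0.49 with an estimated correlation), and the glycolysis call was lost after quantile normalisation (0.054) or cyclic loess (0.052).

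In L1236, PRDM1, IL7R and TC2N had the largest rises among genes whose arms did not overlap. IL7R, the interleukin 7 receptor and a known FOXO1 target of lymphocytes, rose by 4.83 ± 0.17, TC2N by 4.38 ± 0.15 and EPHA4, an ephrin receptor, by 4.25 ± 0.12. IL7R and TC2N started below the floor of 5 (4.54 and 4.52). Counted from the floor, the rise of TC2N was 3.90, below that of EPHA4, so its rank is not firm. CD79A, a chain of the B cell receptor complex, rose by 2.36 ± 0.13, CR2 by 2.26 ± 0.12 and LYZ, lysozyme, by 3.66 ± 0.13. The B cell identity list, which holds CD79A and CR2, was not called in this line (median -0.013, adjusted p = 0.66). F13A1, a coagulation factor subunit, fell by 1.85 ± 0.15, PUS7, a pseudouridine synthase, by 1.57 ± 0.12 and ARHGAP29 by 1.55 ± 0.16. FBXO32, steep in KM-H2 and L428, was not called here (adjusted p = 0.384). In total 3661 genes passed, 1307 higher and 2354 lower, and 133 and 60 of these by at least 1 log2 unit. The balance depended on scaling, with 855 higher and 2765 lower after median centring and 1877 and 1818 after cyclic loess on the tested genes, and without L1236 4-OHT 2 the total was 2378. Lymphocyte migration genes were higher (median 0.45, adjusted p = 3.6e-06, and 0.013 with an estimated correlation). Glycolysis genes (-0.22, 0.013) and unfolded protein response genes (-0.19, 0.044) were called lower, at adjusted p = 0.45 and 0.41 with an estimated correlation. The glycolysis call was lost after cyclic loess (0.083) and the other after every other scaling tried (0.053 to 0.11).

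In UHO-1, PRL, the hormone prolactin, rose by 5.09 ± 0.13 (2.64e-17), P2RY14, a receptor of UDP sugars, by 4.44 ± 0.12 and PLAAT4, a phospholipase, by 3.13 ± 0.12. PRL was called higher in the other 4 lines too, but its levels there stayed below 5 in both arms. SLC2A5, a fructose transporter, fell by 1.08 ± 0.12 and the histone H4 genes H4C14 and H4C15, which share 1 set of values, by 1.02 ± 0.091. In total 3878 genes passed, 2118 higher and 1760 lower, and 143 and 3 of these by at least 1 log2 unit. The balance depended on scaling, with 2448 higher and 914 lower after median centring but 1826 and 2091 after quantile normalisation of all arrays. Leaving out any 1 of the 4 UHO-1 arrays gave between 1857 and 2328 genes. Genes with signals from 5 to 7 were lower in this line as deposited, with a median change of -0.17 over 5474 genes, 733 of them called lower and 316 higher, but after cyclic loess the median was -0.029, with 188 called lower and 470 higher. Insulin and PI3K signalling genes (median 0.16, adjusted p = 0.0026), autophagy genes (0.20, 0.0014), JAK-STAT genes (0.21, 0.0092) and NF-kB target genes (0.14, 0.016) were called higher and MHC class II genes (-0.24, 0.044) and myeloid markers (-0.40, 0.03) lower. None of these held with an estimated correlation (adjusted p = 0.25, 0.32, 0.23, 0.26, 0.43 and 0.32 with an estimated correlation), and those of JAK-STAT, NF-kB and myeloid genes were lost after cyclic loess (0.064, 0.089 and 0.062).

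**Figure D3:**
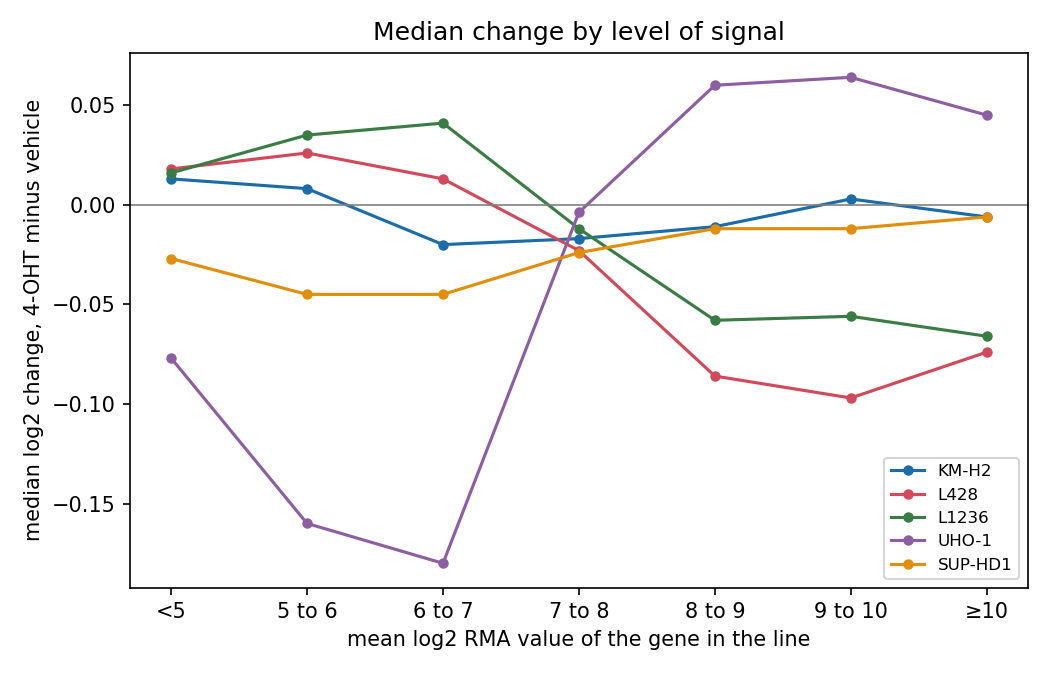
Median log2 change, 4-OHT minus vehicle (vertical axis), of genes grouped by their mean log2 RMA value in a line (horizontal axis), with 1 coloured line per cell line. In UHO-1 the median was -0.18 for genes with signals from 6 to 7 and 0.064 for those from 9 to 10; in L428 it was 0.026 from 5 to 6 and -0.097 from 9 to 10.

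SUP-HD1 had the fewest calls, 956 genes, 583 higher and 373 lower, and 65 and 3 of these by at least 1 log2 unit. PHOSPHO1, a phosphatase of mineralising cells, rose by 2.99 ± 0.13, GPLD1, a phospholipase, by 2.63 ± 0.11 and CXCL16, a chemokine, by 2.61 ± 0.16. HHLA2, an immune checkpoint ligand of the B7 family, fell by 1.11 ± 0.14, GPR183, the oxysterol receptor that positions B cells, by 1.08 ± 0.15 and the chemokine CCL2 by 1.08 ± 0.14 (n = 2 arrays per arm, limma adjusted p of 5.04e-05 or less). Median centring gave 457 higher and 169 lower genes and quantile normalisation 704 and 625. The balance also depended on single arrays, with 549 and 139 without vehicle 1 but 328 and 348 without vehicle 2, and without SUP-HD1 4-OHT 1 or 4-OHT 2 the total was 433 or 451. Insulin and PI3K signalling genes (median 0.047, adjusted p = 0.0049) and autophagy genes (0.11, 0.027) were called higher and S phase genes (-0.22, 6.1e-07), MHC class II genes (-0.21, 0.02) and glycolysis genes (-0.10, 0.027) lower. None of these held with an estimated correlation (adjusted p = 0.27, 0.43, 0.32, 0.37 and 0.51 with an estimated correlation).

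The response differed between lines for 6762 of 15850 genes (F test in limma), of which 4229 were also called on average, and 1359 had a range of at least 1 log2 unit over the lines. The widest ranges were those of LUM (8.92), FBXO32 (5.82), IL7R (5.09), CR2 (4.85), TC2N (4.65), PRDM1 (4.63), PRL (4.60) and EPHA4 (4.52). Some of these sizes rest on signals below the floor, where background limits them. With group means below 5 set to 5, a bound chosen after the values were seen, the ranges were 7.18 for LUM, 4.37 for IL7R, 4.17 for TC2N and 5.05 for PRL, and the other 4 stayed as given. With the same bound the rises were at least 7.18 for LUM and 1.76 for DCN in KM-H2, 4.37 for IL7R, 3.90 for TC2N and 2.93 for LYZ in L1236, 5.05 for PRL in UHO-1 and 1.10 for CD38 in L428. CR2 fell in KM-H2 and rose in L1236. Of 9402 genes called in at least 1 line, 1287 (13.7%) were called in opposite directions in a pair of lines. The mean change of 21 of 25 lists differed between lines, most widely for stromal markers (range 1.5), myeloid markers (1.0) and MHC class II genes (1.0). The first range rested on LUM and DCN in KM-H2, without which it was 0.37, and the myeloid range was 0.58 without LYZ, both computed after the values were seen.

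Pairs of lines shared more calls than independent lists would. The expected counts take every gene as equally likely to be called, yet calls gathered at higher signals. In KM-H2, 1246 genes were called higher and 1370 lower among 7382 with signals of 7 or above, against 346 and 573 among 8468 below. Part of the excess may therefore come from genes that are easier to call in any line. UHO-1 and SUP-HD1 shared 540 called genes where 234 would be shared by independent lists, and 96.1% went the same way. L428 and SUP-HD1 shared 644 where 282 would be, 93.9% the same way, and L428 and UHO-1 1663 where 1140 would be, 92.2% the same way. The lowest shares going the same way were those of KM-H2 with L1236 (65.4% of 1250) and of L1236 with UHO-1 (67.6% of 1076). Across the 15850 genes, which are not independent replicates, Pearson's r of the changes ran from 0.068 for L1236 with UHO-1 to 0.44 for UHO-1 with SUP-HD1 among the 10 pairs. Each line had its own vehicle arrays, so no pair shared controls.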

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

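The tests on LUM, those on probe sets and markers in UHO-1 and the share of opposite calls were chosen only after the results were seen, while those on regrouped arrays, single arrays and the separate normalisation were chosen earlier.

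Differences between lines in the response to 4-OHT stood out for 6762 genes and, of the tested genes given values in the text, for 123 of 130 (F test in limma). Ranges of the log2 change over the 5 lines are given in parentheses. They were widest for LUM (8.92), FBXO32 (5.82), IL7R (5.09), CR2 (4.85), TC2N (4.65), PRDM1 (4.63), PRL (4.6), EPHA4 (4.52), P2RY14 (4.32), ENPP2 (4.23), NTS (4.22), GIMAP4 (4.06), CCL5 (3.85), LYZ (3.72), PLAAT4 (3.7), DCN (3.4), ARHGAP29 (3.33), LGALS2 (3.19), RGS1 (3.13), GCSAM (3) and PHOSPHO1 (3). Next came CXCL16 (2.97), KLF2 (2.89), TNFSF10 (2.86), PMAIP1 (2.85), TP53INP1 (2.73), GPLD1 (2.72), ABLIM1 (2.63), DEPP1 (2.62), SLC2A1 (2.6), GIMAP8 (2.59), CD79A (2.56), SESN3 (2.5), CBLB (2.32), ENTREP1 (2.25), MYC (2.23), EHF (2.19), EPYC (2.13), PLPP3 (2.05), FERMT2 (2.03), SOCS1 (2.01) and F13A1 (2). Intermediate ranges were those of CD38 (1.93), SLC2A5 (1.93), IL4R (1.86), LGR4 (1.82), ABCG2 (1.81), BCL6 (1.76), FCRLA (1.73), HLA-DPB1 (1.73), IFIT2 (1.72), EDEM1 (1.7), CXCR4 (1.69), EBI3 (1.67), H4C14 (1.64), H4C15 (1.64), CD83 (1.53), SLC27A2 (1.49), IFI44L (1.48), TNFRSF8 (1.48), BTG1 (1.46), PUS7 (1.46), HLA-DMB (1.45), SC5D (1.43), FOXP1 (1.41) and EPHB1 (1.4). Smaller ranges were those of BCL2L11 (1.37), LTA (1.37), GPR183 (1.34), IL2RB (1.34), BACH2 (1.31), RGS13 (1.29), BCL11A (1.25), CCR7 (1.23), HLA-DPA1 (1.18), CCL2 (1.17), FSCN1 (1.17), HHLA2 (1.17), DNAJC3 (1.12), INSIG1 (1.1), MARVELD2 (1.05), DHCR7 (1.02) and PIK3IP1 (1.02). Ranges below 1 log2 unit were those of AURKB (0.997), HLA-DMA (0.994), PIM1 (0.927), LYN (0.918), MCM3 (0.909), FOXM1 (0.889), HSPA4L (0.879), GRK5 (0.816), WIPI1 (0.813), MCL1 (0.789), COL1A1 (0.736), RIPOR2 (0.725), WDR43 (0.725), ELL2 (0.723), IGF1R (0.712), TYMS (0.711), CCND2 (0.708), CAD (0.707), FKBP11 (0.702), HK2 (0.68), TNFAIP3 (0.675), MYBBP1A (0.667), BCL2L1 (0.647), EBP (0.646), MCM4 (0.635), PIM2 (0.627), FOXO1 (0.61), MCM2 (0.608), CCR6 (0.605), TFAP4 (0.588), ENO1 (0.576), RICTOR (0.574), CDK4 (0.518), CDKN1B (0.512), MT2A (0.512), PKM (0.488), PDIA4 (0.385), PAICS (0.379), FBL (0.288) and PDIA6 (0.246).

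The mean change of 21 lists also differed between lines. The ranges of these means, of which the stromal one was 0.37 without LUM and DCN and the myeloid one 0.58 without LYZ, were largest for stromal markers (1.5), MHC class II genes (1), myeloid markers (1), B cell identity genes (0.81), lymphocyte migration genes (0.81), germinal centre genes (0.73) and mitosis genes (0.7). They were smaller for Hodgkin cell markers (0.59), S phase genes (0.57), NF-kB target genes (0.55), MYC and ribosome biogenesis genes (0.54), FOXO-induced targets (0.47), interferon-induced genes (0.47) and cholesterol synthesis genes (0.46), and smallest for JAK-STAT genes (0.35), BCL2 family genes (0.33), plasma cell genes (0.28), insulin and PI3K signalling genes (0.26), autophagy genes (0.24), oestrogen-induced genes (0.23) and unfolded protein response genes (0.22).

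Signals were also found in probe sets that entered no comparison of genes. Of 8583 probe sets without a single gene symbol, 1826 were called on average in limma, 1083 higher and 743 lower with 4-OHT, and 504 of these carry several symbols.

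LUM, DCN and EPYC, which lie near each other in the genome, rose together in KM-H2, EPYC by 2.02 log2 units (at least 0.837 from the floor of 5). The nearby BTG1 (1.83) was called higher in the other 4 lines too. CCER1, on the other side of EPYC, was not called (0.03, adjusted p = 0.902) but lay below the floor in both arms (4.56 and 4.59). EPYC, BTG1 and CCER1 were chosen after their values were seen. Stromal cells in the 4-OHT samples were argued against, because the highest change among 6 other stromal markers was 0.28 (COL3A1), 0 of them were called higher and COL1A1 fell by 0.62. A fault of 1 array was argued against too, since LUM read 12.3 and 12.05 in the 2 KM-H2 4-OHT arrays and 3.57 and 3.25 in vehicle. The smallest gap between the arms over the 3 genes was 1.92. LUM was named for arms that did not overlap, and the 3 genes were put together because they rose. That gap therefore cannot decide whether the LUM probe set was at fault. A response of the whole stretch was to raise KERA, between EPYC and LUM, by at least 1 log2 unit, but KERA changed by -0.025. KERA lay below the floor in both arms (3.38 and 3.36), and nothing here shows that its probe set can read the transcript. LUM, DCN and EPYC rose from below the floor, but they were read by other probe sets. No rise of KERA was seen, but this test cannot tell whether the whole stretch responded. An earlier test, in which 0.038% of 15725 windows of 4 neighbours had a mean as high as that around LUM (1.82), was set aside as void, since the window held DCN and EPYC themselves.

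In UHO-1, the 5474 genes with signals from 5 to 7 had a median change of -0.17, which became -0.029 after cyclic loess, with 188 called lower and 470 higher (149 and 509 with loess on the tested genes). A difference between single arrays was argued against, as medians differed by at most 0.039 between the arrays of an arm. An equal offset of all low signals was not decided. In that range 3600 probe sets without a single symbol had a median of -0.058 (95% bootstrap interval -0.067 to -0.047). This median was short of -0.084, which is 50% of the genes' shift before rounding and was the bound set for this test. In every other line, however, such probe sets also had higher medians than the genes. They were -0.0068 against -0.045 in SUP-HD1 and 0.073 against 0.038 in L1236. Without a shared baseline, the bound cannot decide. If low-level transcripts fell in the cells, 16 markers of other cell types in that range were to stay above -0.084. Their median was -0.29 (quartiles -0.40 and -0.18), an outcome that counts against such a fall. The markers lie near the floor, however, so such a fall may contribute but cannot be told apart from background. That reading of the markers, the interval and the quartiles were settled after the values were seen.

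The lines may differ in the response because the 2 sets of arrays were normalised separately, but 3285 genes differed among L1236, UHO-1 and SUP-HD1, within 1 set, and 3684 between KM-H2 and L428, within the other. A single response that varied only in strength was argued against, because 13.7% of the genes called in at least 1 line were called in opposite directions in a pair of lines. That share was counted on the deposited scaling alone. Directions depended on scaling, as in UHO-1 with 2118 higher and 1760 lower as deposited but 2448 and 914 after median centring. Part of the share may therefore come from scaling. Differences between the lines themselves, such as their genetic background or the level of the fusion protein, stay open and were not tested.

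When arrays were regrouped at random within lines, 1 of 100 splits, the real one, called as many genes on average as the 6122 observed. The highest other split called 2199. A split that mixes treated and vehicle arrays puts any difference between the arms into its residual spread, which lowers its calls. The real split is thus favoured if the arms differ for any reason. The 6122 calls against at most 2199 argue against arms that do not differ at all. The test does not tell why they differ, nor how many of the 6122 genes were called by chance. For the 10 lists, 9 of 100 splits, the real one included, called as many, the highest other 12, so chance cannot be excluded for the number of lists.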

How the results depend on the processing

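Both versions of cyclic loess, the floor of 8 and the crossed pairing were chosen after the data were seen; the other settings were planned. Of the comparisons of named genes with their values under other settings, 6306 kept direction and side of the threshold, 268 lost the call, 19 gained it and 6 reversed; for lists the numbers were 838, 47, 23 and 38. The cause was not tested unless fewer arrays, lines or genes entered a fit or a threshold was stricter. Where an arm was left with 1 array, that array was assumed to vary like the other groups. Genes near the floor of 5 are limited by signal over background.

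Leaving out 1 array gave from 2378 to 3781 genes in L1236, 1857 to 4275 in UHO-1, 433 to 1014 in SUP-HD1, 2518 to 3654 in KM-H2 and 3751 to 4825 in L428, and from 5679 to 6236 on average. A change of at least 1 log2 unit left 51 genes on average, 433 in KM-H2, 309 in L428, 193 in L1236, 146 in UHO-1 and 68 in SUP-HD1, and 1359 differing between lines. An adjusted p under 0.01 left 1819 in UHO-1 and 502 in SUP-HD1, and median centring left 626 in SUP-HD1. The lines L1236, UHO-1 and SUP-HD1 alone gave 3979 on average. The 5 lines as replicates gave 0 in limma, with 2373 at an unadjusted p under 0.05. Of 25 lists, 2 were called by camera with an estimated correlation and 18 by fry. Cyclic loess shared 5804 of the average calls and 3002 of those in UHO-1.

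Reversed genes were FOXO1 in KM-H2 and L428 alone (0.00689), IRF4 (0.025), PMAIP1 (-0.0552) and SLC2A1 (-0.186) in the other 3 lines, and, with 1 array or line left out, IRF4 (range -0.0889 to 0.0097) and SLC2A1 (-0.0821 to 0.569). Only SLC2A1 passed the test in both directions.

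Reversed lists, given as mean changes, were not called on average; the direction of the test turned in each, and the mean did not always. With no filter it turned for myeloid markers (0.00783), and after cyclic loess on the tested genes for oestrogen-induced (-0.00183), myeloid (0.0612) and housekeeping genes (0.0243). In KM-H2 and L428 alone it turned for NF-kB targets (-0.0832), oestrogen-induced genes (-0.00839) and T cell markers (-0.0076). In the other 3 lines it turned for B cell (0.0172), mitosis (0.0202), interferon-induced (0.0199), myeloid (0.101), stromal (-0.0215) and housekeeping genes (0.0134). With 5 lines as replicates it turned for oestrogen-induced (-0.0321), myeloid (0.0363) and housekeeping genes (-0.0122). With 1 array or line left out, means ran from -0.198 to 0.00361 for B cell, -0.145 to 0.0293 for mitosis, -0.0332 to -0.0098 for G1, 0.00669 to 0.145 for NF-kB, -0.129 to -0.0108 for interferon-induced, -0.0995 to 0.0154 for cholesterol, -0.0598 to -0.0029 for oestrogen-induced, -0.124 to 0.129 for myeloid and -0.0238 to 0.00703 for housekeeping genes.

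Replicate numbers did not pair the samples in 1 way across lines. Deviations of same-numbered arrays correlated at -0.082 in KM-H2, 0.037 in L428, -0.56 in L1236, 0.29 in UHO-1 and 0.28 in SUP-HD1. Pairing by number in UHO-1 and SUP-HD1, or by crossed numbers in L1236, is therefore possible, and the main fit took no account of it. With the number as a block, 5877 genes were called on average, 3347 in KM-H2, 4524 in L428, 3445 in L1236, 3315 in UHO-1 and 857 in SUP-HD1, 6122 differed between lines and 8 lists were called, without JAK-STAT genes and Hodgkin markers. A block with crossed numbers in L1236 called 4294 genes, 1584 higher and 2710 lower.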

Other observations

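The 9 gene groups described here were looked at after the data were seen, in 54 tests of camera with an estimated correlation, adjusted together, of which 1 passed. The adjustment does not correct for choosing the groups from the same data, so these p-values only describe the groups and are no independent evidence. Enzymes of nucleotide and one-carbon synthesis were lower with 4-OHT in 19 of 19 tested genes (median -0.37, adjusted p = 0.1). Examples, chosen after their values were seen, were PAICS, of purine synthesis, which fell by 0.47 ± 0.03 on average, and CAD, of pyrimidine synthesis, which fell by 0.46 ± 0.034 (SE, n = 10 arrays per arm, limma). In L1236, 5 of 5 genes of the GIMAP family, GTPases of lymphocytes, rose (median 1.7, adjusted p = 0.032). GIMAP4 rose by 3.75 ± 0.11 and GIMAP8 by 2.37 ± 0.13 there, both chosen after their values were seen.

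None of the 9 groups passed as a group on average, and the 1 test passed was that of the GIMAP family in L1236. Among the other 7, of 70 mitochondrial ribosomal proteins 49 fell and 3 rose (adjusted p = 0.12), and 8 of 8 chaperonin subunits fell (0.18). Of 8 metallothioneins, which bind zinc and copper, 7 fell (median -0.20, adjusted p = 0.1), with MT2A down by 0.54 ± 0.027. Of 6 TLR genes 3 rose and 0 fell (0.14), of 16 KLF genes 7 rose and 2 fell (0.27), of 5 IFITM genes 3 fell (0.12) and of 6 GBP genes 3 rose and 0 fell (0.21).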
